A study of Mus musculus with 20 samples.

How the data were processed

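Total RNA from soleus and gastrocnemius of 10 male ICR mice was hybridised to 20 one-colour arrays, 5 per group, after 24 h of free movement or of hind-limb suspension at a head-down tilt of 45°, per the labels. Per the labels' protocols, 600 ng of RNA with spike-in RNA was amplified and labelled with Cy3. The authors' files hold spot intensity on a linear scale from Agilent Feature Extraction 9.1.3.1, per the file headers, with spatial background detrending, multiplicative detrending and surrogate values near background, and with no scaling between arrays. The authors' series table was compared with the scanner values: each of its columns equalled the processed intensity of that array within 0.5%, so it is linear, uncentred and unscaled, and it served as an alternative. A statistical test by the authors is not given in the sources used here. Each array held 45018 spots, of which 43379 were not controls, for 41174 distinct probes. The 75th percentile of the processed intensity ranged from 385.5 to 736.1 between arrays, 80.49% to 92.98% of probes were well above background, and at most 43 spots on an array carried the mark for uneven spots.

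From these values, marked uneven spots were left out, each array was scaled to its 75th percentile over non-control spots, values were taken to log2 and spots of 1 probe were averaged. A probe was kept if well above background on at least 4 of the 5 arrays of 1 group, and each gene was represented by its brightest kept probe, which left 25291 genes. Of the probes with a gene name in the files, 22951 were named through an accession, 6659 through a current symbol and 3109 through an older symbol in the RefSeq gene table, and 8455 kept the name in the file; an older symbol was not used where it is the current symbol of another gene. Levels of different probes were not compared. All changes are relative to the 75th percentile of the array. E1A spike-in probes, whose RNA went into each labelling in the same volume per the labels' protocols, stood at 1.75 ± 0.20 in soleus HLS, 1.49 ± 0.04 in soleus control, 1.77 ± 0.13 in gastrocnemius HLS and 2.55 ± 0.08 in gastrocnemius control (SD, n = 5), so the level of the percentile against the spike-ins differed between groups.

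A means model of the 4 groups over all 20 arrays was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 (package data.table, version 1.17.8), and all tests are two-sided. The contrasts were HLS against control in each muscle, their difference, and soleus against gastrocnemius in controls. Adjusted p is Benjamini-Hochberg over all genes with a threshold of 0.05. For 42 gene lists (31 of pathways and 11 of cell types) camera was run with an inter-gene correlation of 0.01 over genes measured on every array, adjusted over the 42 lists of a contrast, and again with an estimated correlation. With the estimated correlation, the stretch, unfolded protein response and angiogenesis lists in soleus and the stretch, angiogenesis and denervation lists in gastrocnemius kept an adjusted p below 0.05. Where a gene was not well above background on any array of a group, the fold is a lower bound: the mean of the brighter group against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Figures were drawn with matplotlib 3.10.9.

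Apart from the additions named in this paragraph, the comparisons, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule took, for each HLS contrast, the 10 highest and 10 lowest changes among passing genes whose groups did not overlap, 20 genes whatever their values, and from each described list up to 2 passing members at each end, or up to 2 with the lowest p where none passed. For the interaction and the muscle contrast it took the 8 highest and 8 lowest, and for the latter also 6 fibre type genes. Gene lists with slide, scan day or animal as a block were tested after the data had been seen. Slide as a random block in the HLS contrasts and the interaction, and soleus arrays of scan day 2 alone, were also chosen then. Values within slide 5 and scan day 2 without soleus HLS 1, and the place of each array between the control muscles (its median over genes at least 2-fold apart in controls), were also added then. The rule's part on list members was written for the HLS contrasts and was extended to the interaction and the muscle contrast, over all 42 lists, after the data had been seen.

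Per the labels, soleus and gastrocnemius of 1 number within an arm came from 1 animal, so the animal is a block for the interaction and the muscle contrast, while control and HLS animals are different mice. Deviations from the group means of both muscles of 1 animal correlated at -0.344 to 0.169 over 10 animals, with a median of 0.0358. Single genes could still go with the animal: among HLS arrays, Ddit4 and Foxo1 stood highest on HLS 5 in both muscles. Replicate arrays correlated at 0.9711 to 0.9883 within groups, and no array repeated another. The arrays lay on 6 slides scanned on 3 days, and slide and scan day were used as blocks; slide 5 (1 control and 3 HLS arrays of soleus) and slide 2 (3 control arrays and 1 HLS array of gastrocnemius) held both conditions. Alternatives were quantile normalization, normexp background correction with an offset of 50, the series table, no filter, a filter on all 20 arrays, marked spots kept, the mean of the probes of a gene, an intensity trend, array weights, the blocks, the 10 arrays compared alone, and leaving out each array. The limma step was tested on simulated data with 200 changed genes in each of the soleus, gastrocnemius and muscle contrasts. The interaction held the changed genes of both HLS contrasts. The simulated noise was independent between arrays, with no slide or scan day effect. Of genes changed 2-fold the step recovered 83.6% in the soleus contrast, 82.1% in the gastrocnemius contrast, 66.4% in the interaction and 88.1% in the muscle contrast. Of genes changed 1.5-fold it recovered 53.7%, 38.8%, 18.7% and 40.3%, each over 25291 genes. False calls were 20 of 178, 9 of 156, 18 of 258 and 7 of 157 calls in the same order.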

Results

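Transcript levels were measured on 20 one-colour Agilent mouse arrays, each with RNA of 1 muscle of 1 animal. The soleus is a postural muscle rich in slow fibres, and the gastrocnemius is a mixed muscle rich in fast fibres. Male ICR mice aged 6 months either moved freely or spent 24 h in hind-limb suspension (HLS), in which the tail is held up and the hind limbs bear no weight. Each muscle and condition had 5 arrays from 5 animals, and the arrays of both muscles with 1 animal number came from the same mouse. Between 80.49% and 92.98% of probes were well above background on an array, and the number of arrays limits the precision. Changes are log2 differences ± SE from limma, relative to the 75th percentile of each array. Adjusted p is after Benjamini-Hochberg over 25291 genes, or over 42 gene lists.

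The comparison of HLS with control soleus asks how 1 day of unloading alters the transcripts of a postural muscle. Fbxo32, the muscle ubiquitin ligase atrogin-1, rose by 2.17 ± 0.21 (adjusted p = 2.9e-06). Gadd45a, a growth-arrest gene, rose by 2.77 ± 0.26 (adjusted p = 2.4e-06), and Hdac4, a histone deacetylase, by 2.28 ± 0.16 (adjusted p = 6.9e-08). The highest rise was that of Chac1, a glutathione-degrading enzyme, at 3.38 ± 0.48 (adjusted p = 0.00016), which is 10.4-fold. Among genes that fell were the Z-disc protein gene Csrp3 (-2.46 ± 0.37, adjusted p = 0.00025), the actin-binding protein gene Abra (-2.62 ± 0.19, adjusted p = 7.1e-08) and Ankrd1 (-2.36 ± 0.27, adjusted p = 1.6e-05). The largest fall was that of Nmrk2, a nicotinamide riboside kinase of muscle, with a 95% interval of -4.97 to -3.03 (adjusted p = 1.9e-05). Tnfrsf12a, the receptor of TWEAK, fell by 3.13 ± 0.31 (adjusted p = 3.3e-06). In all, 1504 of 25291 genes changed, 611 upward and 893 downward, and 267 of them by at least 2-fold. At an unadjusted p below 0.05 there were 4536 genes, against 1265 expected by chance.

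The other genes of the 10 with the highest rise were Depp1 (2.55), the amino acid transporter Slc43a1 (2.48), Eda2r (2.27), Ddit4l (2.22), Ddit4 (2.14) and Inmt (2.11). The other genes of the 10 with the largest fall were Tnfrsf11b (-2.41), Otud1 (-2.35), the inducible heat shock protein gene Hspa1a (-2.35), Xirp1 (-2.29) and Timp1, an inhibitor of matrix metalloproteinases (-2.24). Slide 5 held 1 control and 3 HLS soleus arrays. Within it Fbxo32 stood at 1.69, Gadd45a at 2.25, Hdac4 at 1.82, Chac1 at 2.91, Csrp3 at -2.66, Abra at -2.57, Ankrd1 at -2.85, Nmrk2 at -3.55 and Tnfrsf12a at -1.97. Within scan day 2, with 5 control and 3 HLS arrays, they stood at 2.18, 2.75, 2.29, 3.47, -2.62, -2.48, -2.28, -3.39 and -2.95. Estimates with slide or scan day as a block were equal to these values. Without HLS 1 the same genes, in that order, stood at 1.54, 2.20, 1.75, 2.75, -1.86, -2.66, -3.22, -4.23 and -2.22 within slide 5. Within scan day 2 without HLS 1 they stood at 2.03, 2.70, 2.22, 3.31, -1.83, -2.57, -2.65, -4.07 and -3.21. Of the 20 genes over all arrays, 5 had an adjusted p below 0.05 with slide as a block and 19 with scan day as a block. The exception with scan day was Ddit4 (1.71, adjusted p = 0.17), which stood at 0.54 within slide 5 (0.24 without HLS 1) and lost its call without HLS array 5 (adjusted p = 0.063).

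Among genes followed whatever their values, the ubiquitin ligase MuRF1 gene Trim63 rose by 1.18 ± 0.32 (adjusted p = 0.034). The cell cycle inhibitor Cdkn1a rose by 1.31 ± 0.34 (adjusted p = 0.025). Ppargc1a, a coactivator of mitochondrial genes, fell by 0.87 ± 0.22 (adjusted p = 0.02), and Ankrd2, a stretch-responsive gene of slow muscle, fell by 1.81 ± 0.25 (adjusted p = 0.00013). Foxo1 (0.47, adjusted p = 0.44), Foxo3 (0.21, adjusted p = 0.68), Mstn (0.98, adjusted p = 0.29), Igf1 (-0.59, adjusted p = 0.18) and Eif4ebp1 (0.41, adjusted p = 0.18) did not pass. Nor did Myog (0.32, adjusted p = 0.51), Mt1 (0.48, adjusted p = 0.48) and Mt2 (0.76, adjusted p = 0.45). The myosin heavy chain genes stood at -0.14 for Myh7 (adjusted p = 0.73), -0.04 for Myh2 (adjusted p = 0.89), 0.37 for Myh1 (adjusted p = 0.2) and 0.31 for Myh4 (adjusted p = 0.89). Myh7, Myh2 and Myh1 read 7.36 to 9.43 over the arrays of both muscles. Whether differences are read in full at such bright levels was not tested. On HLS 1 the slow troponin gene Tnni1 stood at 4.15 against a mean of 6.98 on the other HLS arrays. Myh7 stood there at 8.58 against 8.91 to 9.17. Flat values of these myosin genes therefore do not exclude a change. The level of Myh4 ranged from 4.70 to 8.37 between control arrays and from 4.21 to 9.47 between HLS arrays. Without HLS 1, Mstn stood at 0.37 and Myh4 at -0.39; within slide 5 they stood at 1.66 and 2.19 with that array and at 0.57 and 0.90 without it. Trim63 lost its call without control 2 or 4 or HLS 1, 2 or 5 (adjusted p 0.056 to 0.11), Cdkn1a without control 4 or HLS 1 or 5 (0.063 to 0.071), and Ppargc1a without control 1 or HLS 5 (0.055 to 0.071). Within slide 5, and with slide as a block, Trim63 stood at 0.71, Cdkn1a at 1.55 and Ppargc1a at -1.56, and within slide 5 without HLS 1 at 0.33, 0.99 and -1.67. All 4 calls were lost with slide as a block (adjusted p = 0.9 for Trim63, 0.56 for Cdkn1a, 0.11 for Ppargc1a and 0.18 for Ankrd2). Within scan day 2, and with scan day as a block, they stood at 1.29 (adjusted p = 0.081), 1.44 (adjusted p = 0.026) and -0.71 (adjusted p = 0.18), and Ankrd2 stood at -1.82 (adjusted p = 0.0016).

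Gene lists fixed before the data were examined were compared with all other genes by camera. Of 47 stretch-responsive muscle genes 16 fell in soleus, led by Abra, Csrp3 and Ankrd1, and Pdlim7 rose by 0.60, a call lost without control 4 (adjusted p = 0.06); 23 and 1 passed when adjusted over the list alone. The list's median was -0.37, with adjusted p = 8.9e-18, and adjusted p = 0.022 with an estimated correlation. Of 46 heat shock proteins and chaperones 14 fell, led by Hspa1a and Dnajb4 (-1.80), and 1 rose (17 and 1 adjusted over the list alone). The test gave adjusted p = 7.3e-10, and adjusted p = 0.14 with an estimated correlation. The unfolded protein response list had 11 of 29 members down, among them Atf3 (-1.78) and the chaperone gene Hspa5 (-0.93), while Chac1 and 1 other rose (15 and 2 adjusted over the list alone). Its adjusted p was 1.9e-08, and adjusted p = 0.035 with an estimated correlation (0.073 without HLS 1). Extracellular matrix genes fell in 13 of 53 cases and rose in none, with Timp1 and the metalloproteinase gene Adamts1 (-1.10) as examples (18 and 1 adjusted over the list alone). Their adjusted p was 8.1e-12, and adjusted p = 0.16 with an estimated correlation. Slow fibre genes fell in 6 of 23 cases, led by Csrp3 and Ankrd2 (8 down and 1 up adjusted over the list alone). Their median was -0.51, with adjusted p = 3.6e-08, and adjusted p = 0.2 with an estimated correlation. This fall rested in part on HLS 1, where Tnni1 stood at 4.15 against a mean of 6.98 on the other HLS arrays: without it 5 genes fell and the median was -0.16 (adjusted p = 4.2e-05, and adjusted p = 0.32 with an estimated correlation). Within slide 5, and with slide as a block, the medians were -0.41 for stretch, -0.26 for heat shock, -0.18 for unfolded protein, -0.32 for matrix and -0.40 for slow fibre genes. Within scan day 2, and with scan day as a block, they were -0.27, -0.19, -0.37, -0.18 and -0.68. HLS 1 was 1 of the 3 HLS arrays in both; without it the medians were -0.49, -0.36, -0.01, -0.24 and -0.01 within slide 5 and -0.35, -0.29, -0.25, -0.11 and -0.05 within scan day 2.

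Glucocorticoid receptor targets rose in soleus in 9 of 29 cases and fell in none, with Gadd45a and Ddit4 highest (18 up and 1 down adjusted over the list alone). Their median was 0.69, with adjusted p = 7.8e-09, and adjusted p = 0.16 with an estimated correlation. FoxO targets rose in 10 of 31 cases and fell in none (15 and 1 adjusted over the list alone). Their median was 0.37, with adjusted p = 4.2e-05, and adjusted p = 0.27 with an estimated correlation. Of 39 autophagy and lysosome genes 9 rose, including the autophagosome coat gene Map1lc3b (1.03 ± 0.15), and none fell (11 and 2 adjusted over the list alone). The list's adjusted p was 0.0076, with adjusted p = 0.41 with an estimated correlation and 0.13 with normexp. Of 24 E3 ubiquitin ligases of atrophy, Fbxo32, Fbxo31 (1.55), Trim63 and 1 other rose and Asb5 (-1.32) fell (6 and 1 adjusted over the list alone). With slide as a block, as within slide 5, Asb5 stood at -0.51 (adjusted p = 0.9) and Fbxo31 at 1.12 (adjusted p = 0.53). With scan day as a block they stood at -0.95 (adjusted p = 0.089) and 1.35 (adjusted p = 0.0034). Camera gave the list an adjusted p of 0.037, with adjusted p = 0.41 with an estimated correlation, 0.29 with normexp and 0.054 with the 10 soleus arrays alone. None of 34 proteasome subunits passed in limma, over all genes or adjusted over the list alone; Psmd4 stood at 0.43 (adjusted p = 0.15) and the list had an adjusted p of 0.99. Circadian clock genes rose in 5 of 21 cases, with Tef at 1.06 (7 adjusted over the list alone). Their median was 0.38, with adjusted p = 0.0035, and adjusted p = 0.34 with an estimated correlation. Tef stood at 0.22 within slide 5 and with slide as a block (adjusted p = 0.95), and at 1.04 with scan day as a block (adjusted p = 0.039).

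Within slide 5 the medians of these soleus lists were 0.24 for glucocorticoid targets, 0.32 for FoxO targets, 0.08 for autophagy, -0.01 for E3 ligases, -0.01 for proteasome subunits and -0.05 for clock genes. With slide as a block they were the same except for FoxO targets (0.28) and E3 ligases (-0.02), and the autophagy (adjusted p = 0.3), E3 ligase (adjusted p = 0.36) and clock (adjusted p = 0.74) calls were lost. Within scan day 2, and with scan day as a block, the medians were 0.45, 0.33, 0.16, 0.11, 0.07 and 0.26. Without HLS 1 they were 0.24, 0.30, 0.05, 0.02, -0.06 and 0.00 within slide 5 and 0.43, 0.54, 0.09, 0.08, -0.01 and 0.22 within scan day 2. Over all slides, the glucocorticoid median was 0.44 without HLS 5, and that of clock genes 0.13 without control 2 and 0.24 without HLS 4. Leaving out control 2 ended the calls of autophagy (adjusted p = 0.14) and clock genes (adjusted p = 0.053), and leaving out control 2, HLS 1 or HLS 2 ended that of the E3 ligases (0.064 to 0.19).

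In soleus, growth arrest, immediate-early, fibre, metabolic and immune lists also passed. Growth arrest and p53 targets rose in 9 of 27 cases and fell in 2 (12 and 3 adjusted over the list alone), with adjusted p = 0.03, and adjusted p = 0.33 with an estimated correlation. Immediate-early genes fell in 6 of 29 cases, among them Nr4a1 (-1.79), while Klf10 rose (8 and 2 adjusted over the list alone), with adjusted p = 3e-04, and adjusted p = 0.18 with an estimated correlation. Fatty acid genes rose in 7 of 43 cases and fell in 2 (9 and 4 adjusted over the list alone), with adjusted p = 0.014, and adjusted p = 0.57 with an estimated correlation. Cell cycle genes fell in 4 of 29 cases and rose in 1 (5 and 2 adjusted over the list alone), with adjusted p = 0.031, and adjusted p = 0.51 with an estimated correlation. Of 23 fast fibre genes 2 rose (2 adjusted over the list alone), with a median of 0.22 and adjusted p = 0.037, and adjusted p = 0.64 with an estimated correlation. That call did not hold without HLS 1, whose fibre type genes stood apart (median 0.00, adjusted p = 0.6), with normexp (adjusted p = 0.47) or with the 10 soleus arrays alone (adjusted p = 0.078). Calcium handling genes fell in 3 of 36 cases and rose in 1 (4 and 4 adjusted over the list alone), with a median of -0.02 and adjusted p = 0.037, and adjusted p = 0.57 with an estimated correlation. Inflammation genes fell in 3 of 36 cases (5 down and 1 up adjusted over the list alone), with a median of 0.00 and adjusted p = 0.046, and adjusted p = 0.41 with an estimated correlation. Oxidative phosphorylation subunits fell in 2 of 65 cases (0 adjusted over the list alone), with a median of -0.02 and adjusted p = 0.028, and adjusted p = 0.67 with an estimated correlation. Macrophage markers had 0 of 15 past the threshold, also over the list alone, with a median of -0.16 and adjusted p = 0.037, and adjusted p = 0.6 with an estimated correlation. Calls were lost without control 2 or HLS 2 for p53 targets (0.052 to 0.12), control 2 or 4 or HLS 2 for fatty acid (0.066 to 0.3), control 2 or 4 or HLS 1 for cell cycle (0.053 to 0.2) and control 2, 3 or 4 or HLS 1, 3 or 4 for fast fibre genes (0.073 to 0.6). They were also lost without control 1 or 5 or HLS 2 or 5 for calcium handling (0.052 to 0.51) and oxidative phosphorylation (0.064 to 0.77), control 2 or 4 or HLS 1, 2 or 4 for inflammation (0.061 to 0.19) and control 3, 4 or 5 or HLS 1 or 5 for macrophage markers (0.057 to 0.38). Slide as a block gave an adjusted p of 0.065 for p53 targets, 0.15 for immediate-early genes, 0.46 for fatty acid, 0.27 for cell cycle, 0.3 for fast fibre, 0.74 for inflammation and 0.3 for macrophage genes. With scan day as a block it was 0.069 for cell cycle, 0.58 for calcium, 0.97 for oxidative phosphorylation and 0.25 for macrophage genes. Normexp gave 0.15 for p53 targets and 0.29 for fatty acid genes, and quantile normalization 0.23 for calcium, 0.12 for oxidative phosphorylation, 0.08 for inflammation and 0.07 for macrophage genes. The fast fibre median was 0.07, 0.12, 0.12 and 0.09 without control 3, 4 or 5 or HLS 4. The macrophage median was -0.25 and -0.27 without control 2 or HLS 3, and -0.10, -0.07 and -0.07 without control 4, HLS 1 or HLS 5.

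Markers of other cells moved beside these groups in soleus. Tendon markers had a median of -0.28 with 2 of 11 down, including the tendon transcription factor gene Scx at -0.78 (2 adjusted over the list alone). The test gave these genes an adjusted p of 0.0035, with adjusted p = 0.41 with an estimated correlation and 0.073 without HLS 5. Fibroblast markers had a median of -0.20 with 2 of 14 down, including Mfap5 at -0.99 (2 adjusted over the list alone). For the list, adjusted p was 0.012, with adjusted p = 0.51 with an estimated correlation and 0.062 to 0.27 without control 4, HLS 1 or HLS 5. Smooth muscle and pericyte markers had a median of -0.20 with 2 of 12 down, including Tagln at -1.20 (3 adjusted over the list alone). By camera the adjusted p was 0.014, with adjusted p = 0.41 with an estimated correlation and 0.19 without HLS 5. Schwann cell and nerve markers had a median of -0.30 with 0 of 14 past the threshold, also when adjusted over the list alone. Their adjusted p was 0.019, with adjusted p = 0.57 with an estimated correlation and 0.053 to 0.07 without control 1 or 2 or HLS 2 or 5. Within slide 5, and with slide as a block, the medians were -0.49 for tendon, -0.04 for fibroblast (adjusted p = 0.1), -0.29 for smooth muscle and 0.49 for Schwann cell markers (adjusted p = 0.021, in the opposite direction). Within scan day 2, and with scan day as a block, they were -0.31, -0.24 (adjusted p = 0.071), -0.15 (adjusted p = 0.18) and -0.28 (adjusted p = 0.078). Without HLS 1 the medians were -0.58, 0.08, -0.16 and 0.17 within slide 5 and -0.30, -0.01, 0.05 and -0.54 within scan day 2. With quantile normalization the fibroblast (adjusted p = 0.05) and smooth muscle (adjusted p = 0.08) calls were lost. Leaving out 1 array moved the fibroblast median to -0.08 (control 4), -0.11 (HLS 1) or -0.12 (HLS 5), that of smooth muscle to -0.32 (control 2), -0.12 (control 4) or -0.12 (HLS 5), and that of Schwann cell markers to -0.47 (HLS 1).

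**Figure D1:**
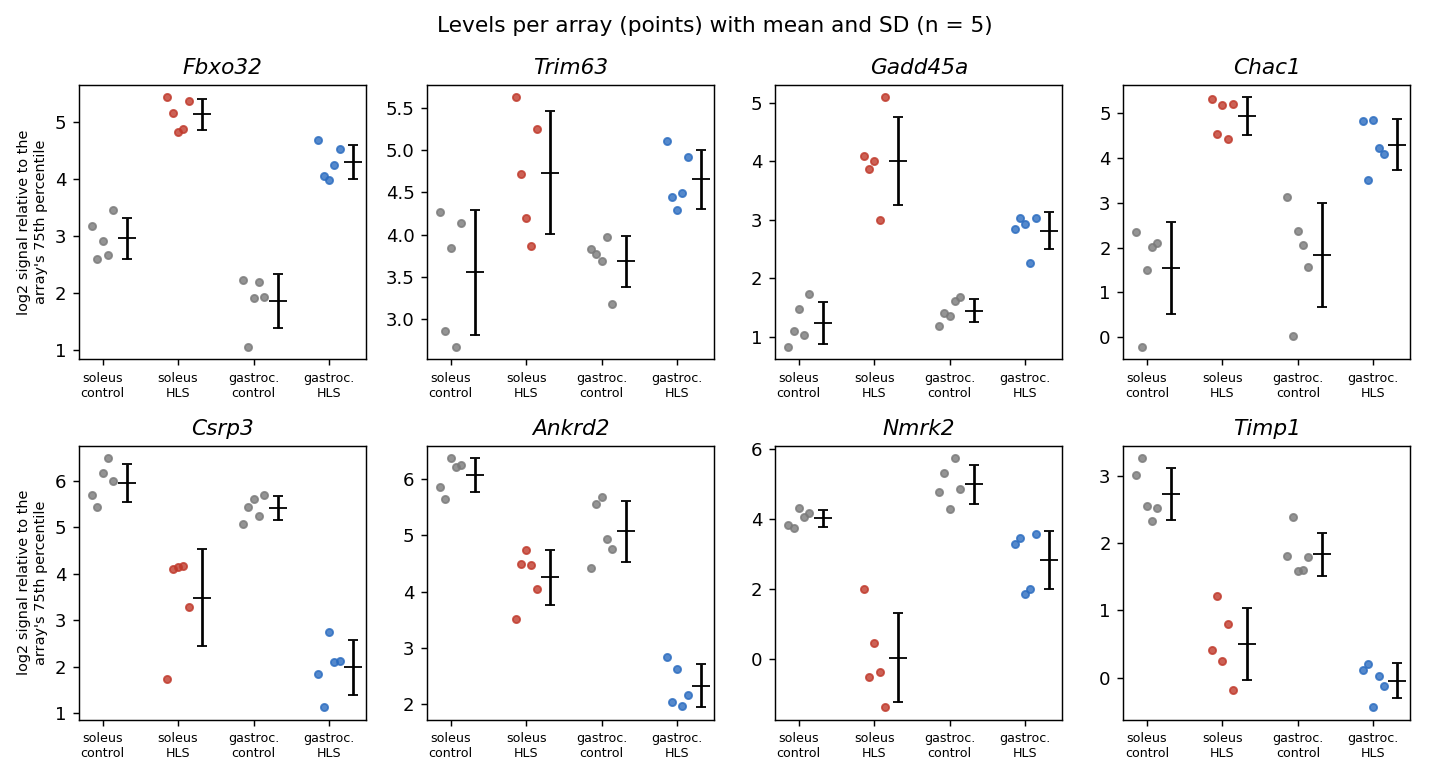
Each point is 1 array and the bar gives mean and SD (n = 5 arrays per group) of the log2 signal relative to the 75th percentile of the array, for 8 genes in control and HLS muscle. Fbxo32, Gadd45a and Chac1 lay higher on every HLS array than on every control array of the same muscle, and Csrp3, Ankrd2, Nmrk2 and Timp1 lay lower.

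The same question was put to the gastrocnemius. Csrp3 fell furthest, by 3.42 ± 0.37 (adjusted p = 2.4e-05), and Ankrd2 fell by 2.74 ± 0.25 (adjusted p = 4.8e-06). Tnfrsf12a fell by 2.68 ± 0.31 (adjusted p = 4.4e-05), and Lmcd1, a LIM domain transcriptional regulator, by 2.24 ± 0.24 (adjusted p = 2.3e-05). Fbxo32 rose by 2.43 ± 0.21 (adjusted p = 2.8e-06), and Ddit4, an inhibitor of mTORC1, by 2.55 ± 0.53 (adjusted p = 0.0087). Chac1 rose by 2.48 ± 0.48 (adjusted p = 0.0057), Cdkn1a by 1.76 ± 0.34 (adjusted p = 0.0055) and the glucocorticoid-induced immunophilin gene Fkbp5 by 1.73 ± 0.35 (adjusted p = 0.0065). In all, 801 of 25291 genes changed, 295 upward and 506 downward, and 142 of them by at least 2-fold. Spike-in probes differed by -0.78 between HLS and control gastrocnemius and by 0.26 in soleus. The balance of rises and falls in each muscle therefore depends on the point to which the arrays were scaled. At an unadjusted p below 0.05 there were 3708 genes. Leaving out control 2 left 444 genes, and leaving out HLS 5 left 499.

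The remaining genes of the 10 highest rises in gastrocnemius were Depp1 (1.85), Inmt (1.80), Gadd45g (1.66), the transporter gene Slc10a6 (1.62) and Slc43a1 (1.60). Of the 10 largest falls, others were Ankrd1 (-2.23), Nmrk2 (-2.17), Xirp1 (-2.14), Prnd (-1.97) and Timp1 (-1.88). Tnfrsf11b ranked with them by a value not well above background on any HLS gastrocnemius array and well above it on 3 control arrays; as a bound it was at least 1.60-fold lower (adjusted p = 0.00011). Slide 2 held 3 control arrays and 1 HLS array of the gastrocnemius. Within it Csrp3 stood at -3.68, Ankrd2 at -2.29, Tnfrsf12a at -1.99, Lmcd1 at -2.28, Fbxo32 at 2.67, Ddit4 at 2.24, Chac1 at 2.83, Cdkn1a at 3.06 and Fkbp5 at 0.82. Within scan day 1, with 5 control arrays and 1 HLS array, they stood at -3.57, -2.23, -2.10, -2.25, 2.82, 2.30, 3.00, 2.97 and 0.76. Estimates with slide or scan day as a block were equal to these values, and 2 of the 20 genes had an adjusted p below 0.05 with slide and 3 with scan day as a block. The Depp1 call was lost without control 2, 4 or 5 or HLS 1, 3 or 5 (adjusted p 0.062 to 0.1), and that of Inmt without control 2 or 3 or HLS 5 (0.053 to 0.062).

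Of the genes followed whatever their values, Gadd45a rose in gastrocnemius by 1.37 ± 0.26 (adjusted p = 0.0055). The myogenic transcription factor gene Myog rose by 0.93 ± 0.23 (adjusted p = 0.026), and Eif4ebp1, a repressor of cap-dependent translation, by 0.65 ± 0.17 (adjusted p = 0.037). Trim63 (0.96, adjusted p = 0.12), Foxo1 (0.51, adjusted p = 0.46), Foxo3 (0.19, adjusted p = 0.77), Mstn (0.29, adjusted p = 0.87), Igf1 (-0.38, adjusted p = 0.51) and Ppargc1a (-0.73, adjusted p = 0.084) did not pass. Nor did Mt1 (0.90, adjusted p = 0.15), Mt2 (1.22, adjusted p = 0.21), Myh7 (-0.03), Myh2 (-0.14), Myh1 (-0.01) and Myh4 (0.03). With the 10 gastrocnemius arrays alone Trim63 (adjusted p = 0.014) and Ppargc1a (adjusted p = 0.01) passed. The Myog call was lost without control 1, 2 or 5 or HLS 2, 4 or 5 (0.053 to 0.078), and the Eif4ebp1 call without control 2, 3, 4 or 5 or HLS 1, 3, 4 or 5 (0.052 to 0.12). Within slide 2, and with slide as a block, Gadd45a stood at 1.29, Myog at 0.58 and Eif4ebp1 at 0.66, and these calls were lost with slide as a block (adjusted p = 0.53, 0.84 and 0.71). Within scan day 1, and with scan day as a block, they stood at 1.39, 0.90 and 0.69, and the calls were lost as well (adjusted p = 0.36, 0.58 and 0.54).

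Among the lists, 15 of 47 stretch-responsive genes fell in gastrocnemius and 1 rose, Pdlim5 at 1.08 (20 and 1 adjusted over the list alone). Their median was -0.35, with adjusted p = 3.2e-19, and adjusted p = 0.032 with an estimated correlation. Of 46 heat shock proteins and chaperones 9 fell, including Hspa1a (-1.68) and Dnaja4 (-1.29), and none rose (17 adjusted over the list alone). The list's adjusted p was 2.3e-09, and adjusted p = 0.099 with an estimated correlation. Of 53 matrix genes 9 fell, including the collagen chaperone gene Serpinh1 (-1.13), and none rose (18 adjusted over the list alone). Camera gave an adjusted p of 2.3e-10, and adjusted p = 0.15 with an estimated correlation. The unfolded protein response list had 5 of 29 down, with Hspa5 at -0.76, and Chac1 up (8 and 1 adjusted over the list alone). Its adjusted p was 7.8e-06, and adjusted p = 0.085 with an estimated correlation. Slow fibre genes had 5 of 23 down (8 adjusted over the list alone) and a median of -0.18, with adjusted p = 7.2e-05, and adjusted p = 0.39 with an estimated correlation. Over the members measured on every array the median was -0.20, and it was -0.07 without control 3 (adjusted p = 0.0024), -0.12 without HLS 1 and -0.11 without HLS 4. Cell cycle genes had 5 of 29 down, led by the cyclin D1 gene Ccnd1 (-1.67) and the replication factor gene Mcm5 (-1.06), and none up (8 down and 1 up adjusted over the list alone). The test gave these genes an adjusted p of 6e-05, and adjusted p = 0.23 with an estimated correlation. Within slide 2 the medians were -0.26 for stretch, -0.15 for heat shock, -0.30 for matrix, -0.20 for unfolded protein, -0.43 for slow fibre (-0.41 with slide as a block) and -0.31 for cell cycle genes. Within scan day 1 they were -0.29, -0.17, -0.27, -0.09, -0.32 (-0.26 with scan day as a block) and -0.32, and the other medians were equal with the blocks.

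Glucocorticoid receptor targets rose in gastrocnemius in 9 of 29 cases, led by Ddit4 and Cdkn1a, and fell in none (17 adjusted over the list alone). Their median was 0.75, with adjusted p = 1.1e-12, and adjusted p = 0.075 with an estimated correlation. FoxO targets rose in 8 of 31 cases and fell in none (14 adjusted over the list alone). Their median was 0.31, with adjusted p = 1.2e-08, and adjusted p = 0.099 with an estimated correlation. The denervation and neuromuscular junction list had 4 of 28 up, including Hdac4 (1.29), and the postsynaptic adaptor gene Dok7 down at -0.76 (4 and 1 adjusted over the list alone). Its median was 0.14, with adjusted p = 0.0065, and adjusted p = 0.039 with an estimated correlation. In soleus 5 were up and 2 down, also over the list alone, with a median of 0.07 and no call (adjusted p = 0.065, and 0.045 with quantile normalization), and the interaction of the list had an adjusted p of 0.97. Of 24 E3 ligases, Fbxo32 passed (4 adjusted over the list alone), with a median of 0.07. For the list, adjusted p was 0.018, with adjusted p = 0.39 with an estimated correlation and 0.052 to 0.15 without control 5, HLS 1 or HLS 5. None of 34 proteasome subunits passed in limma, over all genes or adjusted over the list alone, with Psma5 at 0.31 (adjusted p = 0.16). Their median was 0.05 (adjusted p = 0.29), against an adjusted p of 0.015 with quantile normalization, 0.00082 with slide as a block and 2.3e-05 with scan day as a block. Within slide 2, and with slide as a block, the medians were 0.59 for glucocorticoid targets, 0.51 for FoxO targets, 0.22 for denervation genes, 0.24 for E3 ligases and 0.22 for proteasome subunits. Within scan day 1, and with scan day as a block, they were 0.62, 0.59, 0.21, 0.23 and 0.26.

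In gastrocnemius, growth arrest, clock and metabolic lists also passed. Growth arrest and p53 targets rose in 7 of 27 cases and fell in 1 (8 and 2 adjusted over the list alone), with adjusted p = 0.018, and adjusted p = 0.26 with an estimated correlation. Clock genes rose in 2 of 21 cases (3 adjusted over the list alone), with a median of 0.11 and adjusted p = 0.013, and adjusted p = 0.45 with an estimated correlation. Fatty acid genes had a median of 0.17 with 2 of 43 down (7 up and 3 down adjusted over the list alone), with adjusted p = 0.013, and adjusted p = 0.67 with an estimated correlation. Oxidative phosphorylation subunits fell in 1 of 65 cases (0 adjusted over the list alone), with a median of -0.09 and adjusted p = 0.0012, and adjusted p = 0.67 with an estimated correlation. Of 39 autophagy genes 4 rose (6 adjusted over the list alone), and the list did not pass (median 0.04, adjusted p = 0.073). It passed with scan day (adjusted p = 0.0037) or slide (adjusted p = 0.012) as a block, with quantile normalization (adjusted p = 0.011) and with normexp (adjusted p = 0.044). Calls were lost without HLS 3 for p53 targets (adjusted p = 0.058), control 2 for clock genes (adjusted p = 0.06), control 2 or 5 or HLS 3 for fatty acid genes (0.051 to 0.12) and HLS 2 for oxidative phosphorylation (adjusted p = 0.06). Slide as a block gave an adjusted p of 0.14 for clock, 0.2 for fatty acid and 0.18 for oxidative phosphorylation genes, and with scan day as a block 0.084, 0.082 and 0.34; quantile normalization gave 0.054 for oxidative phosphorylation. Leaving out 1 array moved the clock median to 0.18, 0.05, 0.07, 0.19 and 0.17 (control 1 to 5) or 0.17 (HLS 5), that of fatty acid genes to 0.11 (control 5) and that of oxidative phosphorylation to -0.05 (HLS 2).

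Beside these groups, tendon markers had a median of -0.20 in gastrocnemius with 2 of 11 down, including Scx at -0.75 (2 adjusted over the list alone). By camera the adjusted p was 0.073, and with slide as a block, as within slide 2, their median was -0.56 (adjusted p = 0.0039). Smooth muscle and pericyte markers had a median of -0.16 with 1 of 12 down (2 adjusted over the list alone). Their adjusted p was 0.018, with adjusted p = 0.5 with an estimated correlation and 0.093 with quantile normalization, and their median was -0.24 with slide as a block (adjusted p = 0.2). Schwann cell and nerve markers had a median of -0.22 with 0 of 14 past the threshold, also when adjusted over the list alone (adjusted p = 0.41). With slide as a block, as within slide 2, their median was -0.88 (adjusted p = 0.0012). Within scan day 1, and with scan day as a block, the medians were -0.51 for tendon (adjusted p = 0.0036), -0.21 for smooth muscle (adjusted p = 0.29) and -0.81 for Schwann cell markers (adjusted p = 0.0036).

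**Figure D2:**
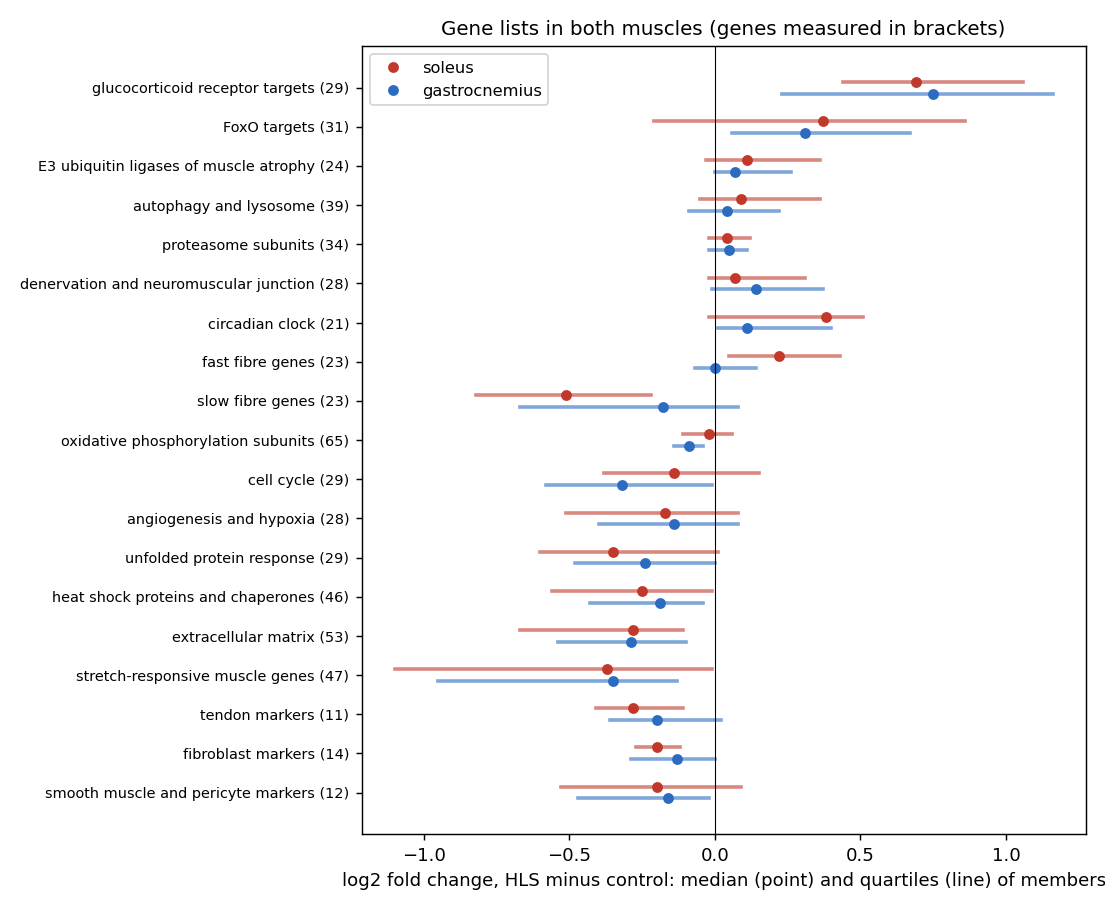
Points are the median and lines the quartiles of log2 fold changes (HLS minus control) of the members of 19 gene lists and cell type marker lists in soleus and gastrocnemius, with the number of genes measured in brackets. Glucocorticoid receptor targets stood highest in both muscles (medians 0.69 and 0.75), and stretch-responsive genes had medians of -0.37 and -0.35.

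Set side by side, the muscles moved many of the same genes in the same direction. Fbxo32, Chac1, Ddit4, Depp1, Slc43a1 and Inmt were among the 10 highest rises in both. Csrp3, Nmrk2, Tnfrsf12a, Ankrd1, Xirp1 and Timp1 were among the 10 largest falls in both. Of genes past the threshold, 158 rose in both muscles, where independent lists would share 7.13, and 359 fell in both, where they would share 17.9. None of the 25291 genes passed limma's threshold in both muscles with opposite signs, against 12.2 and 10.4 for independent lists. Both muscles came from the same animals, so the lists are not independent, and these overlaps were not set against splits of the animals. Of the 1504 genes changed in soleus, 94.9% had the same sign in the gastrocnemius, and of the 801 changed in the gastrocnemius, 93.8% had the same sign in soleus. Across genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.556 and a Spearman coefficient of 0.385, with a covariance of 0.0467. When HLS labels were exchanged over whole animals, 1 of 100 splits, the real one, gave values as large. The permutation p was thus 0.01 for each measure, the smallest that 100 splits can give, and the highest other values were 0.461, 0.367 and 0.0261.

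A test of the difference between the muscles' responses (the interaction) found 2 genes. The response of Dnmt3a, a DNA methyltransferase gene, differed by -1.53 ± 0.18 (adjusted p = 0.001), with -0.38 in soleus and 1.15 in gastrocnemius. That of Nlrc3, a NOD-like receptor family member, differed by -1.38 ± 0.22 (adjusted p = 0.041), with -1.59 and -0.20. The Dnmt3a value came from 1 of 3 probes, and the other probes gave -0.18 ± 0.18 and 0.08 ± 0.16. The other probe of Nlrc3 gave -1.17 ± 0.34. At an unadjusted p below 0.05 there were 1456 genes, against 1265 expected by chance. Immediate-early genes had a median interaction of -0.27 with 0 of 29 past limma's threshold (1 down adjusted over the list alone), with Ccn1 at -1.42 (adjusted p = 0.3) and Nr4a1 at -1.70 (adjusted p = 0.54). The list's adjusted p was 0.0025, with adjusted p = 0.98 with an estimated correlation, 0.37 with slide as a block and 0.15 with scan day as a block. Without gastrocnemius HLS 3 its median was -0.18 (adjusted p = 0.013). The other 41 lists had adjusted p above 0.05 over all arrays with no block. The proteasome list passed with slide (median -0.20, adjusted p = 0.034) or scan day (-0.23, adjusted p = 0.019) as a block and with normexp (adjusted p = 0.021). Schwann cell markers passed with slide as a block (median 1.32, adjusted p = 1.9e-05) and, in the opposite direction, without soleus HLS 1 (median -0.31, adjusted p = 0.035). With normexp the heat shock (adjusted p = 0.0076), unfolded protein response (adjusted p = 0.019) and matrix (adjusted p = 0.038) lists passed as well.

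With slide as a block Dnmt3a stood at -1.29 (adjusted p = 0.83) and Nlrc3 at -0.96 (adjusted p = 1). With scan day as a block they stood at -1.28 (adjusted p = 0.22) and -1.43 (adjusted p = 0.43), and no batch held all 4 groups. With the animal as a fixed block the adjusted p was 0.05 for Dnmt3a and 0.067 for Nlrc3, so that limma called 0 genes with any of these 3 blocks. The Nlrc3 call was lost without any 1 of 15 arrays (adjusted p 0.054 to 0.12). These were gastrocnemius control 1, 2, 4 and 5, gastrocnemius HLS 1, 2, 3, 4 and 5, soleus control 1, 3 and 4 and soleus HLS 3, 4 and 5. The count was 13 without soleus HLS 1, and 4 without soleus control 2 or 5. It was 1 without gastrocnemius control 1, 2, 4 or 5, gastrocnemius HLS 1, 2, 3 or 4, soleus control 1 or 3 or soleus HLS 3, 4 or 5.

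The muscles of control animals were compared as a reference for fibre type. Slow-muscle genes were higher in soleus, among them Sln, a regulator of the sarcoplasmic calcium pump (4.60 ± 0.59, adjusted p = 1.4e-05), Tpm3 (4.04 ± 0.36, adjusted p = 6.8e-07) and the slow troponin genes Tnnc1 (3.88 ± 0.46, adjusted p = 8e-06) and Tnni1 (3.76 ± 0.43, adjusted p = 5.7e-06). The slow calcium pump gene Atp2a2 (3.49 ± 0.38, adjusted p = 3.4e-06) and the slow myosin gene Myh7 (1.45 ± 0.17, adjusted p = 5.7e-06) were also higher. Lower in soleus were Mss51 (-5.18 ± 0.69, adjusted p = 2.1e-05), the fast-fibre actinin gene Actn3 (-4.32 ± 0.71, adjusted p = 0.00016) and Mstn, which encodes myostatin (-3.75 ± 0.48, adjusted p = 1.5e-05). Pvalb, a calcium buffer of fast fibres (-3.30 ± 0.74, adjusted p = 0.0022), and the fast myosin gene Myh4 (-2.24 ± 0.79, adjusted p = 0.034) were lower as well. Myh6 (3.03), Hp (3.16) and the lipid droplet gene Cidec (3.00) were among the 8 highest, and Cdh4 (-3.61), Lrp2bp (-2.76) and Ighm (-2.69) among the 8 lowest. Pcdhga12, not well above background on any soleus control array, was at least 2.05-fold lower (adjusted p = 2.4e-06). Myh1 stood at 0.07 (adjusted p = 0.76). Myh2 (0.36, adjusted p = 0.0059) and Tnni2 (0.35, adjusted p = 0.01) passed, but stood at 0.07 (adjusted p = 0.56) and 0.01 (adjusted p = 0.91) with quantile normalization. In all, 8484 of 25291 genes differed, 3203 higher and 5281 lower in soleus, and 1108 of them by at least 2-fold, with 11058 at an unadjusted p below 0.05.

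No slide held both muscles, so muscle and slide cannot be told apart in this comparison, and no scan day held controls of both muscles. With scan day as a block, where the step between the days of the controls rests on gastrocnemius HLS 1 (day 1) against gastrocnemius HLS 2 to 5 (day 2), Tpm3 stood at 3.51 (adjusted p = 0.013), Sln at 5.90 (adjusted p = 0.0094), Myh7 at 1.17 (adjusted p = 0.053), Actn3 at -4.10 (adjusted p = 0.12) and Myh4 at -1.84 (adjusted p = 0.56). The Myh4 call was lost without any 1 of the gastrocnemius controls or without soleus control 2, 3 or 5 (adjusted p 0.051 to 0.095). Its level was 8.37 on soleus control 1 and 7.90 on soleus control 4, against 4.70 to 5.84 on the other soleus controls. The share of calls lower in soleus was 62.2%, and 52.7% with quantile normalization (4184 of 7944).

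Of 23 slow fibre genes 19 were higher in soleus and 1 lower, the same adjusted over the list alone. Their median was 1.26, with adjusted p = 4.3e-15, and adjusted p = 0.14 with an estimated correlation. Of 23 fast fibre genes 13 were lower and 5 higher, the same adjusted over the list alone. Their median was -0.89 with adjusted p = 0.078, against 0.042 with the animal as a block, 0.027 with the 10 control arrays alone and 2.6e-05 with quantile normalization. Fatty acid uptake and oxidation genes were higher in 28 of 43 cases and lower in none, including Angptl4, an inhibitor of lipoprotein lipase (2.00), with 28 adjusted over the list alone. Camera gave an adjusted p of 9.6e-14, and adjusted p = 0.21 with an estimated correlation. Glycolysis and glycogen genes were lower in 21 of 36 cases, including Gpd1, 4.01-fold lower, and the muscle glycogen phosphorylase gene Pygm (-1.93), and higher in 5, including Ldhb (1.64), the same adjusted over the list alone. The test gave these genes an adjusted p of 0.0067, with adjusted p = 0.56 with an estimated correlation and 0.12 with scan day as a block. Oxidative phosphorylation subunits were higher in 19 of 65 cases and lower in none (17 adjusted over the list alone), with a median of 0.13. For the list, adjusted p was 1.3e-05, with adjusted p = 0.56 with an estimated correlation and 0.55 with quantile normalization. Beside these, adipocyte markers had 11 of 14 higher, including the adiponectin gene Adipoq (2.52), and 1 lower, the same adjusted over the list alone. Their median was 0.92, with adjusted p = 3.1e-06, and adjusted p = 0.28 with an estimated correlation.

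FoxO targets were higher in control soleus in 17 of 31 cases and lower in 1, the same adjusted over the list alone (adjusted p = 1.3e-05, and adjusted p = 0.4 with an estimated correlation). Angiogenesis and hypoxia genes were higher in 10 of 28 cases and lower in 1, the same adjusted over the list alone (adjusted p = 0.005, and adjusted p = 0.064 with an estimated correlation). Stretch-responsive genes were higher in 16 of 47 cases and lower in 9 (18 and 12 adjusted over the list alone), with adjusted p = 0.012, and adjusted p = 0.56 with an estimated correlation. That call was lost without gastrocnemius control 5 (adjusted p = 0.062) and with quantile normalization (adjusted p = 0.66). The matrix (adjusted p = 0.013), unfolded protein response (adjusted p = 0.015) and fibroblast (adjusted p = 0.011) lists were higher in soleus, with adjusted p = 0.62, 0.55 and 0.56 with an estimated correlation. Without soleus control 4 they stood at 0.054, 0.052 and 0.05, and with quantile normalization at 0.55, 0.55 and 0.3. Endothelial markers were higher in 6 of 14 cases and lower in none, the same adjusted over the list alone (adjusted p = 0.005, and adjusted p = 0.55 with an estimated correlation; 0.12 with quantile normalization). Inflammation genes were higher in 10 of 36 cases and lower in 4, the same adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.55 with an estimated correlation), and 0.05 without soleus control 4. Immediate-early genes were higher in 7 of 29 cases and lower in 5, the same adjusted over the list alone (adjusted p = 0.049, and adjusted p = 0.56 with an estimated correlation), and lost the call without gastrocnemius control 4 or 5 or soleus control 1 or 4 (0.05 to 0.13), with quantile normalization (adjusted p = 0.34) and with scan day as a block (adjusted p = 0.13).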

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

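The tests of the background level of the slides, of what the filter on all arrays keeps, of values within a slide or with a block without soleus HLS 1 and of lone arrays among genes of the muscle contrast were chosen only after the results they bear on were seen.

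Changes shared by the muscles after HLS may come from unloading or from differences between slides. Genes changed in the gastrocnemius, signed by that change, had a median of 0.48 in soleus within slide 5 (0.59 over all soleus arrays, and 0.44 within slide 5 without soleus HLS 1), against at most 0.27 between arrays of 1 group on 1 slide. Genes changed in soleus had a median of 0.39 in the gastrocnemius within slide 2 (0.41 over all its arrays), against at most 0.13. Both argue against slides as the whole cause. Of 100 splits of the soleus arrays 1, the real one, gave as many genes (1504, highest other 24). Of 100 splits of the gastrocnemius arrays 1 did (801, highest other 2). The other splits mix control and HLS arrays, so genes changed by HLS widen the spread in them. Most control and HLS arrays also lay on different slides, so the arrays cannot be freely exchanged. The splits thus argue against no difference at all between the real groups, but cannot exclude chance for the size of the counts. Stress of the suspension itself was not tested apart from unloading.

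In controls 62.2% of calls were lower in soleus, and the share was 83.7%, 84.1%, 76.9%, 49.1% and 23.8% from the dimmest to the brightest of 5 equal groups of genes. The median differences of these groups were -0.21, -0.18, -0.11, 0.02 and 0.15, so the share also depends on the point to which the arrays were scaled. Scaling to the spike-ins was not tested. A signal difference of dim probes stays open: the share was 60.7% among probes well above background on all arrays, above the 55% it was written to leave at most, but that filter kept 97.7% and 99.8% of the next 2 groups after the dimmest, and the 52.7% with quantile normalization is evened by construction. Negative control spots were lower on soleus control arrays by -0.64 (exact permutation p = 0.0079, n = 5), but that difference would shift the next-to-dimmest group by -0.035 against a measured -0.18. A difference of the size read on these spots thus falls short of the whole shift. Their processed intensity is detrended and holds surrogate values near background, so it cannot bound a background difference of the slides, which stays open. Of 100 splits of the control arrays 1, the real one, gave as many genes (8484). The highest other gave 1910 and exchanged 1 array of each muscle, and the 11 others that parted all animal pairs gave at most 2. These other splits put both muscles in each group, so genes that differ between the muscles or their slides widen the spread in them. The splits thus argue against no difference at all between the real groups, but cannot exclude chance for the size of the count. Muscle and slide cannot be told apart because no slide held both muscles, and a difference between the tissues stays open as well.

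Dnmt3a (-1.53) and Nlrc3 (-1.38) differed in their HLS response between the muscles by the interaction test. For Dnmt3a a fault of 1 probe is a candidate explanation, since the other probe with the lowest p gave -0.18 ± 0.18 (SE), although a transcript read by that probe alone would look the same. A slide difference is argued against as the whole cause by -1.29 ± 0.35 (SE) with slide as a block (-1.17 ± 0.35 without soleus HLS 1); that call ended because the SE grew, since few arrays share a slide. Of 100 splits of the animals 1, the real one, gave as many genes (2, highest other 1), over all arrays with no block. The other splits mix control and HLS animals, so genes changed by HLS in both muscles widen the spread in them. They therefore cannot exclude chance for the interaction count. The count was 0 with the animal as a block and 1 without any 1 of 13 arrays, no higher than that other split, and splits were not drawn for those settings.

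A lone array stood apart from the other 4 of its group in 18 of 214 groups of arrays tested. Chance gives about 1 in 20 for a single group. The groups are not independent, since several slow-muscle genes stood apart together on 1 array, so the count cannot be read against that rate. In log2 relative to the 75th percentile, soleus HLS 1 stood apart in Sln (2.74, others 6.65), Tpm3 (3.46, others 5.74), Tnnc1 (4.09, others 6.95), Tnni1 (4.15, others 6.98), Atp2a2 (3.49, others 5.97), Myh6 (5.05, others 7.26) and Ddit4l (6.70, others 5.19). Gastrocnemius control 3 did in Sln (3.04, others 1.74), Tnni1 (4.18, others 3.06), Tpm3 (2.64, others 1.53) and Mt2 (3.01, others 1.55). The others were Foxo1 on soleus HLS 5 (3.06, others 1.77), Fbxo32 on gastrocnemius control 2 (1.06, others 2.06), Timp1 on gastrocnemius control 2 (2.38, others 1.70), Gadd45g on gastrocnemius HLS 2 (5.06, others 6.29), Gadd45a on gastrocnemius HLS 4 (2.26, others 2.95), Inmt on gastrocnemius HLS 5 (2.11, others 1.29) and the spike-in level on gastrocnemius HLS 1 (2.01, others 1.71). Spike-in probes, which the comparisons do not use, differed by 0.26 between HLS and control soleus, by -0.78 between HLS and control gastrocnemius and by -1.05 between soleus and gastrocnemius of controls (exact permutation p = 0.0079 each, n = 5 per group). That test takes no account of slides, and no slide held both muscles. Within slide 5 the soleus control stood at 1.53 and the HLS arrays at 1.73, 1.58 and 1.55, against 2.01 and 1.90 for the HLS arrays on slide 6. Within slide 2 the gastrocnemius controls stood at 2.50 to 2.65 and HLS 1 at 2.01.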

How the results depend on the processing

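Slide as a random block in the HLS contrasts and the interaction, soleus arrays of scan day 2 alone, and gene lists with slide, scan day or animal as a block were chosen after seeing the data. The soleus count (1504) became 22 with slide as a block, 776 with scan day as a block, 705 with the 10 soleus arrays alone and 895 with scan day 2 alone; leaving out 1 array gave 1059 to 1532. The gastrocnemius count (801) became 1820 with array weights, 10 with slide and 16 with scan day as a block; leaving out 1 array gave 444 to 663. Few arrays share a slide or day across conditions, so these blocks also widen the errors. The interaction count (2) became 6 with quantile normalization, 4 with normexp, 1 with no filter, 8 with probes well above background on all arrays, 0 with the mean of probes, 9 with an intensity trend, 7 with array weights, 0 with slide, 0 with scan day and 6 with slide as a random block; leaving out 1 array gave 1 to 13. The muscle count (8484) became 1374 with scan day as a block; leaving out 1 array gave 7080 to 8683. The correlation of fold changes (0.556) kept its permutation p of 0.01 in all its alternatives, from 0.482 with no filter to 0.652 with probes well above background on all arrays; leaving out 1 array gave 0.518 to 0.556. Causes were not tested.

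With the animal as a fixed replicate block the interaction gave 0 genes and the muscle contrast 7801, and as a random block 2 and 8447. Of the lists in both contrasts, those of fast fibre genes (adjusted p = 0.042) and tendon markers (adjusted p = 0.033) gained a call in the muscle contrast with the animal as a fixed block. The number 1 to 5 as a block, which pairs no animals in the HLS contrasts (same-numbered control and HLS arrays correlated at -0.305 to 0.167), gave 1502 soleus and 820 gastrocnemius genes.

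A value counts as reversed here if its sign turned and it passed in the main or the other setting. For lists the direction given by camera was used. Genes that passed in neither setting were not counted. The reversed values, with the cause not tested, were as follows. With the mean of all probes of a gene, Nip7 in soleus HLS stood at 0.00, and in the muscle contrast Ubqln1 at -0.07, Akt1 at -0.04, Csnk1d at -0.09, Oaz2 at -0.14 and Dsp at 0.02. With slide as a block, Thbs1 in soleus HLS stood at 0.06, the circadian clock list at -0.05, and the Schwann cell and nerve list at 0.49 in soleus HLS and 1.32 in the interaction. With scan day as a block, Cilp2 stood at -0.01 and Mkx at -0.19 in the muscle contrast. With quantile normalization the proteasome list stood at -0.16 in the muscle contrast. Probes near background limit the precision of dim genes.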

Other observations

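Leaving out each array was planned. Tests of gene lists with a block, the hypotheses about soleus HLS 1 and other tests without it were chosen only after the result was seen. Further signalling genes changed in both muscles. Irs1, an adaptor of insulin and IGF1 receptors, fell by 2.03 ± 0.25 in soleus (adjusted p = 3.5e-05) and by 1.48 ± 0.25 in gastrocnemius (adjusted p = 0.002), and stood at -1.19 within slide 5 and -0.78 within slide 2. Vegfa, an angiogenic growth factor, fell by 1.51 ± 0.21 (adjusted p = 0.00011) and 1.20 ± 0.21 (adjusted p = 0.0023), and stood at -1.36 and -0.89 within those slides. Rcan1, an inhibitor of calcineurin, fell by 2.17 ± 0.24 (adjusted p = 1.2e-05) and 1.80 ± 0.24 (adjusted p = 0.00021), and stood at -1.36 and -1.32. Klf10, a TGF-beta-induced transcription factor gene, rose by 1.28 ± 0.18 (adjusted p = 0.00011) and 1.05 ± 0.18 (adjusted p = 0.0017), and stood at 1.06 and 0.98. With slide as a block all 4 calls were lost in both muscles, with adjusted p in soleus and gastrocnemius of 0.49 and 0.73 for Irs1, 0.23 and 0.52 for Vegfa, 0.35 and 0.3 for Rcan1 and 0.37 and 0.38 for Klf10. With scan day as a block they were lost in gastrocnemius (0.58, 0.36, 0.2 and 0.19) and kept in soleus (0.00079, 0.0024, 4e-04 and 0.0015). The angiogenesis and hypoxia list had 6 of 28 members down and 1 up in soleus (8 and 2 adjusted over the list alone). Its adjusted p was 0.00083, and adjusted p = 0.022 with an estimated correlation. In gastrocnemius 2 were down (8 adjusted over the list alone), with adjusted p = 0.0034, and adjusted p = 0.035 with an estimated correlation. With slide as a block, as within slide 2, its gastrocnemius median moved from -0.14 to -0.06 (adjusted p = 0.12), and with scan day as a block to -0.07 (adjusted p = 0.21); in soleus the medians were -0.17, -0.15 and -0.11. Without gastrocnemius HLS 5 the gastrocnemius median was -0.09 (adjusted p = 0.0072).

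The slow fibre list fell in soleus while slow myosin Myh7, whose bright levels may not show differences in full, did not pass (-0.14, adjusted p = 0.73). A hypothesis was that members shared with the stretch and heat shock lists carried the list. Without Ankrd2, Csrp3, Cryab, Hspb6 and Fhl2 its camera p was 4e-04 with the preset correlation and 0.15 with an estimated one, and its median moved from -0.51 to -0.28. The first value argues against the shared members as the whole cause, and the second leaves the remaining genes open. Another hypothesis was that soleus HLS 1 alone carried the list. Without that array the list kept an adjusted p of 4.2e-05 (0.32 with an estimated correlation), which argues against it as the whole cause, but the median moved to -0.16. Without both that array and the shared members the camera p was 0.035 and the median -0.07, so little of the fall remained outside them.

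In genes higher in soleus, soleus HLS 1 lay nearer to gastrocnemius than the other soleus arrays. On a scale from 0 for control gastrocnemius to 1 for control soleus, its median place was 0.42 over 323 genes at least 2-fold higher in soleus and 0.76 over 774 genes at least 2-fold lower. Other soleus arrays lay at 0.71 to 1.13 and 0.63 to 1.10, with the lowest values on HLS 5, and gastrocnemius arrays at -0.05 to 0.15 and -0.10 to 0.05. An exchange of the muscles of 1 animal is argued against by gastrocnemius HLS 1, which lay at 0.03. RNA of gastrocnemius in the sample may explain the place, with a soleus share on the linear scale of 0.30 from the genes higher in soleus and 0.83 from the genes lower in soleus. Over genes at least 4-fold apart, 25 higher and 49 lower, its shares were 0.05 and 0.31, nearer to gastrocnemius, where the other soleus HLS arrays had 0.38 to 1.09 and 0.93 to 1.01. The shares differ between gene sets, and muscle goes with slide in these gene sets, so such an admixture, a wrong label or sample from outside the series, and a shift of fibre type in that animal cannot be told apart. Tnnc1 and Sln stood at 0.01 and 0.04 after HLS without that array, against -0.56 and -0.74 with it. Neither value passed. Some fast-muscle genes parted other soleus arrays too. In log2, Myh4 stood at 9.47 on HLS 1, 8.37 on control 1, 7.90 on control 4 and 8.51 on HLS 4. It stood at 4.21 to 5.99 on the other soleus arrays and 8.35 to 8.96 on gastrocnemius arrays. Mss51 stood at 3.14, 2.09, 1.14 and 1.91, against -1.38 to 0.53. Actn3 did not part them so (3.32 on control 4, 4.18 on control 5).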
